A study of Drosophila melanogaster with 12 samples.

How the data were processed

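RNA was sequenced from Drosophila melanogaster guts in 12 libraries. A set of 8 libraries came from pharate adult males (fully formed adults still inside the pupal case) and included the Malpighian tubules, the kidney-like organs attached to the gut. It held 4 groups of 2 libraries: the control strains FRT19A and W1118, a point mutant allele of Hinfp and a deletion allele of Hinfp. The other 4 libraries came from adult intestines, 1 each of an FRT19A control, the Hinfp deletion mutant, that mutant with Hinfp overexpressed and that mutant with the linker histone His1 overexpressed. Groups were taken from the sample titles and characteristics. The labels' design text gave 50 guts per sample, 25 °C culture, flies aged 5 to 6 days for controls and 8 to 9 days for mutants and rescues, and 100 bp reads. Age and genotype therefore cannot be told apart from the labels alone.

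In the pharate set each group had 1 library titled SE and 1 titled PE, taken as replicates 1 and 2. The 2 tags were read as single-end and paired-end libraries, but the label texts did not spell them out. Library preparation was described differently in different label fields, as removal of ribosomal RNA in the series' design text and as poly-A selection in the extract protocol. Nothing in the labels said that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

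The pharate gene and transposable element tables hold the authors' deposited read counts, whole numbers per gene or per element family, which were used without change. Reads were aligned with STAR 2.5.3a and counted with featureCounts 1.5.2 against BDGP6 and dm6, per the submitters' processing notes. The adult tables hold the authors' deposited counts and deposited log2 fold changes of each genotype against the adult control. For those, Trimmomatic 0.39, Bowtie2 2.3.5, STAR 2.5.3a, featureCounts 1.6.2, edgeR 3.28.1 and DESeq2 are named per the submitters' processing notes, without the role of each. The authors' deposited tables of pharate comparisons also hold log2 fold changes and adjusted p-values, which were only described. Strandedness of the counting, and how reads matching several places were treated, are not given in the sources used here. Families of near-identical copies (the histone gene cluster, Stellate genes, transposable elements) can share reads, so their values carry that uncertainty. Multi-copy histone genes stood in the deposited table as 1 row per histone type, among them HIS1 for the linker histone.

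The gene table held 16524 rows, of which 16403 matched a gene symbol, and the element table held 159 rows. Another 72 columns of per-sample TPM values in the authors' comparison tables were left unused, because the counts of the same libraries carry the depth. The authors' separate TPM and FPKM tables and a sign-turned copy of the W1118 comparison were also left out. Coordinates were taken from the Ensembl release 115 annotation of BDGP6.

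Gene counts were tested with edgeR 4.0.16 quasi-likelihood tests in R 4.3.3 (two-sided), after filterByExpr with a minimum count of 10 and TMM scaling, with Benjamini-Hochberg adjustment at 0.05. Element counts were scaled with the library sizes and TMM factors of the genes, because scaling on the elements would remove a rise of most of them, and were adjusted among the elements alone. The main comparison set 4 mutant against 4 control libraries as 2 classes. Each allele was compared with FRT19A, W1118 with FRT19A and the alleles with each other in 1 fit of 4 groups. A gene list was tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists tested. Standard errors of log2 fold changes were the fold change divided by the square root of the F statistic. The comparisons, tests, 38 gene lists, alternatives and rule for naming genes were fixed before the data were examined. The lists cover gut cell types, neighbouring tissues, digestive enzymes, histones, small RNA pathways, immunity, stress, growth and developmental age, and each list's result is given in the report.

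Named genes were Hinfp and the linker histone in every case. Further genes were the 10 with the largest rise and the 10 with the largest fall among genes with an adjusted p under 0.05, a mean log2 CPM of at least 2 and a change in the same direction in each allele against each control. For elements the mean log2 CPM limit was 0. For each list described, the rule took the 3 members with the smallest adjusted p, or the 2 with the highest mean where none passed. In the adult table the rule ran on the authors' deposited adjusted p-values, used there only to choose names and not printed, since each genotype had 1 sample. Genes named outside this rule are marked as chosen after their values were seen.

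Replicate numbers carried the SE or PE tag, so the 8 pharate libraries were checked for pairing before any calls were compared. Libraries with the same number deviated together from their group means, with correlations across genes from 0.651 to 0.851 over all pairs of groups. The first principal component, 58.3% of the variance, separated SE from PE libraries. A fit with the replicate number as a block was therefore run, and its values stand beside the main ones where it changed a described call or moved a count of calls by over 1.5 times. Libraries of a group differed far beyond sampling noise (chi-square per degree of freedom 419 to 612), so all were kept as separate libraries. Since each pair set SE against PE, this spread does not show that its libraries came from separate RNA. Testis marker medians in SE and PE libraries were 12.0 and 0.675 CPM in FRT19A and 10.9 and 0.337 CPM in W1118. They were 14.6 and 13.0 CPM in the point mutant and 24.8 and 10.5 CPM in the deletion mutant. Such unlike gaps argue against a fixed SE to PE difference on the same RNA in every group.

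Agreement of the alleles was measured as the correlation of log2 fold changes across genes, with 10 simulated draws of unchanged groups against the shared controls. Adult libraries had 1 sample per genotype, so no test was run there. List medians in the adult set were placed as percentiles among 10000 random lists of the same size matched on expression in 20 bins. Shares of counts in the adult libraries carry 95% Wilson intervals and single counts carry exact Poisson intervals. Where a control had 0 counts, folds used a floor of 3 counts. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

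Alternatives were the replicate block, DESeq2 1.42.0 size factors and DESeq2's own test, no filter on low counts, a fold size limit of 1 on the log2 scale, leaving out each library in turn, SE or PE libraries alone, other controls, only the compared groups in the fit, the mean of the groups of each class in the fit of 4 groups, and other scaling of the elements. DESeq2 with the block, list tests on SE or PE libraries alone, list tests and allele agreement without each library, and allele agreement with the block were added after seeing the data. The closing section gives their effects.

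The gene and element tests were run on simulated data with known changes drawn from the real means and spreads, with 200 changed genes (40 changed elements) in each of 5 draws. For mutants against controls the fit without the block recovered 29% of genes changed 4-fold and 0.4% of genes changed 2-fold among 13244 genes, and the blocked fit recovered 55.8% and 13.2% with 3.90% false calls. For the deletion against FRT19A, 0% and 0% were recovered without the block, and 14% of 4-fold and 0.2% of 2-fold changes with it, where 12.3% of calls were false. Among 146 elements, 1% of 4-fold and 0% of 2-fold changes were recovered without the block, and 90% and 42% with it, where 7.69% of calls were false. By camera of limma, over 12984 genes, a simulated raised list had an unadjusted p = 7.74e-36 and an unchanged list 0.529. For the adult lists, independent normal values with the spread of the adult mutant's log2 changes stood in for the real ones. There, 200 genes shifted by 1 on the log2 scale reached the percentile 100 and 200 unshifted genes 16.6, out of 12590 genes. Genes were simulated independently in both list checks, so these do not cover lists whose members move together.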

Results

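The series measured RNA in guts of Drosophila melanogaster carrying mutant alleles of Hinfp, a zinc finger gene on the X chromosome whose vertebrate counterpart controls histone gene transcription. Guts with Malpighian tubules of pharate males gave 8 libraries: 2 of each of the control strains FRT19A and W1118, 2 of a point mutant and 2 of a deletion mutant. Adult intestines gave 4 more libraries, 1 per genotype. Gene counts in the pharate libraries ranged from 21924226 to 28740669 and those in the adult libraries from 17991664 to 20271512. In each pharate group 1 library was titled SE (replicate 1) and the other PE (replicate 2). These tags went with large differences: 7SL RNA, the RNA of the signal recognition particle, chosen after its values were seen, had 12 to 26 counts in SE libraries and 708677 to 868286 in PE libraries.

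The targeted gene was examined in each library to check the labels. Hinfp (FBgn0025635, BDGP6 chromosome X, 625542 to 628016, plus strand) stood at 13.4 ± 3.39 CPM in controls and 7.35 ± 1.91 CPM in mutants (SD, n = 4 each). Mutant levels were 66.1% of control in SE libraries and 47.4% in PE libraries. The log2 fold change was -0.87 (SE 0.27), with an adjusted p = 0.0837 by edgeR with Benjamini-Hochberg adjustment, so the transcript difference did not pass the test. The fit with the replicate number as a block gave -0.84 and an adjusted p = 0.0302 by edgeR with Benjamini-Hochberg adjustment. Against FRT19A alone the deletion mutant had a Hinfp log2 fold change of -1.12 (edgeR, Benjamini-Hochberg adjusted p = 0.265) and the point mutant -0.50 (0.641).

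Linker histone transcripts were almost lost from the mutants. HIS1, the row that adds up the copies of the gene for histone H1, which binds the DNA between nucleosomes, fell by 7.07 on the log2 scale (SE 1.67), with an edgeR Benjamini-Hochberg adjusted p = 0.0353 (blocked fit -5.90, 0.00796). Its level went from 195.7 to 1.08 CPM in PE libraries and from 5.09 to 0.404 CPM in SE libraries. The core histone rows, which encode the nucleosome's own proteins, stayed closer to control in PE libraries: HIS2A at 55.7%, HIS2B at 48.7%, HIS3 at 56.7% and HIS4 at 81.4% of the control mean. In SE libraries, with far fewer histone counts, the same rows stood at 59.5%, 121%, 274% and 39.5%. HIS1 had only 3 and 19 counts in the SE mutant libraries. Over all libraries none of these 4 core histones passed the edgeR test (list median log2 -0.83, camera adjusted p = 0.743 after Benjamini-Hochberg adjustment), and 6 replication-independent histone genes, which supply histones outside S phase, had a median of 0.09 with 0 called (camera adjusted p = 0.946). In PE libraries alone 3 of the 4 core histones were called lower (median -0.80, camera adjusted p = 0.0497 after Benjamini-Hochberg adjustment, at the preset correlation only), and in SE libraries alone 0 (median -0.26, 0.948). The blocked fit called 1 of the core histones lower and, of the replication-independent genes, 1 higher and 1 lower. The edgeR call of HIS1 was lost without any mutant library or without replicate 2 of FRT19A or W1118, with Benjamini-Hochberg adjusted p from 0.0745 to 0.107.

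**Figure D1:**
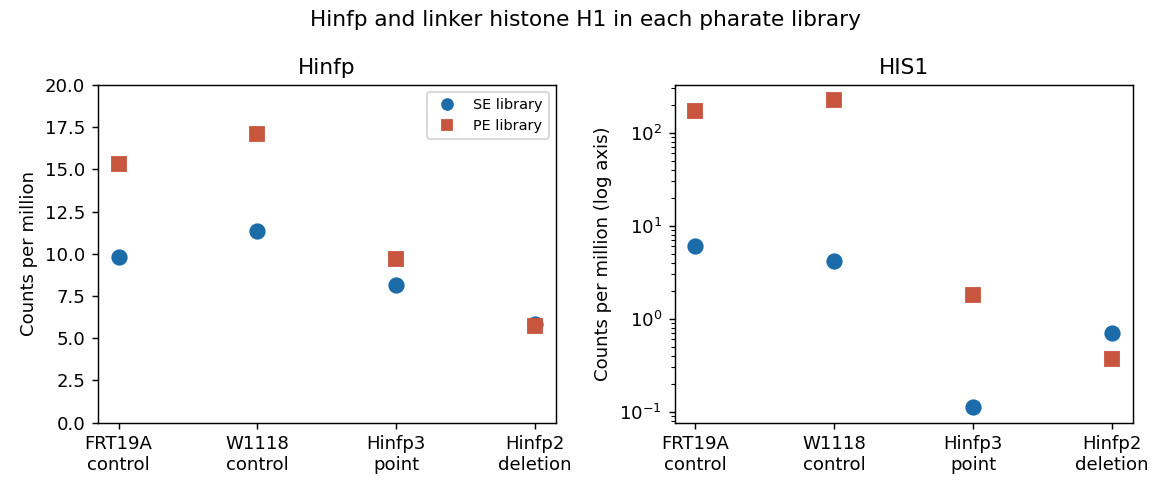
CPM of Hinfp and HIS1 in each pharate library, by group, with SE and PE libraries marked. HIS1 stands at 195.7 CPM in the mean of PE controls and 1.08 CPM in the mean of PE mutants.

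Transposable element RNA took up far more of the mutant libraries. Element counts equalled 0.848% and 2.20% of gene counts in the SE and PE libraries of FRT19A, 2.86% and 6.25% in W1118, 11% and 19.7% in the point mutant and 11.7% and 21.2% in the deletion mutant. Of 146 families tested, 124 had a positive change, the median log2 fold change was 1.66, and 47 families rose and 0 fell by edgeR with Benjamini-Hochberg adjustment (67 at an unadjusted p under 0.05; 68 by DESeq2). The blocked fit called 93 higher and 3 lower. When scaling was set on the elements themselves, which centres them on 0, the calls were 31 higher and 22 lower.

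**Figure D2:**
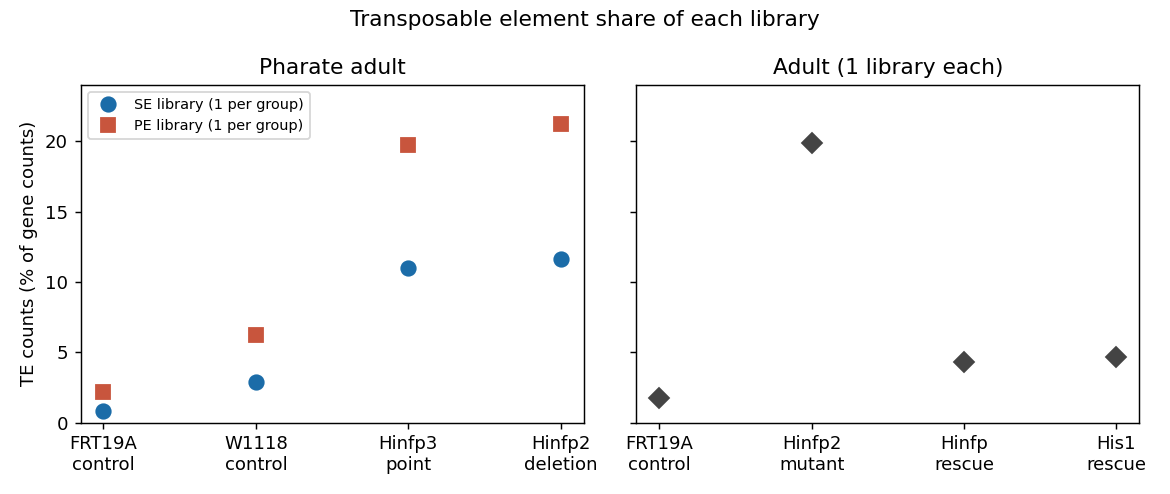
Transposable element counts as a percent of gene counts in each pharate library, with SE and PE libraries marked. Mutant libraries lie between 11% and 21.2% and control libraries between 0.848% and 6.25%.

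The families with the largest rise included G_element, a LINE-like retrotransposon (log2 6.85, SE 0.84, edgeR Benjamini-Hochberg adjusted p = 0.000348), gypsy12, an LTR retrotransposon (6.31, 0.00207), and GATE (6.10, SE 0.69, 0.000306). Next came aurora_element (6.10), the DNA transposon Bari1 (5.89; blocked fit 4.23), Stalker3 (5.78), Dsim_ninja (5.76), accord2 (5.32), a family named only by a number (5.02) and gypsy12_2 (4.95). Each row of the element table was counted as a family, gypsy12 and gypsy12_2 among them. Rows can share reads, so the families named and counted here need not be independent. The level of Bari1 in mutants was 24.7 and 36.2 CPM in SE libraries and 1818 and 1862 CPM in PE libraries. By class, 27 of 57 LTR families (median 2.38), 13 of 33 LINE-like families (2.16), 2 of 23 DNA transposons (0.38) and 5 of 33 unclassified families (0.42) were called higher. The blocked fit called 43, 28, 10 and 12 higher, and 1 lower in each class but the LTR elements. Relative to the other families, LTR elements stood higher (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00400) and DNA transposons and unclassified families lower (0.00162 and 0.0124), with LINE-like elements at 0.0638 (higher at 0.0167 in the blocked fit, and adjusted p = 0.268 with an estimated correlation there), and with an estimated correlation no class differed (adjusted p = 0.546 with an estimated correlation for each). SE libraries alone gave a median of 2.22 over 139 families and 78 calls, and PE libraries alone 1.56 over 143 families and 86 calls. copia, an LTR retrotransposon chosen after its values were seen, made up 57.7% to 74.5% of element counts in all libraries except those of FRT19A (13.7% and 14.8%). Its log2 change between mutants and controls was 2.72 (SE 1.33, edgeR Benjamini-Hochberg adjusted p = 0.134; blocked fit 2.85, 0.0509).

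Among genes, some that encode secreted stress and immune peptides were among the largest rises in the mutants. TotZ and TotC belong to the Turandot family of secreted stress proteins, and TotC stood at 0.400 to 3.21 CPM in controls, while Drsl3, a Drosomycin-like peptide gene, stood at 0.146 and 0.675 CPM in FRT19A and 6.25 and 8.43 CPM in W1118. TotZ had 0 counts in controls and 4979 in mutants, at least 1814-fold higher against a floor of 3 counts over the group (edgeR Benjamini-Hochberg adjusted p = 0.0139; 0.0503 without the point mutant's replicate 2, 0.0516 without the deletion mutant's replicate 2). TotC rose by 8.30 on the log2 scale (adjusted p = 0.00567 by edgeR with Benjamini-Hochberg adjustment) and Drsl3 by 8.16 (0.0112). Other large rises were those of CG30289 (8.60), CG6403 (8.59), lncRNA:CR45180 (7.75), CG14499 (7.65), SteXh:CG42398, a Stellate gene (7.63), lncRNA:CR46253 (7.49) and the odorant receptor gene Or42b (7.30). Falls among the genes that met the naming rule included those of CG7900 (-4.53), CG4576 (-4.29), Ugt37A3, a UDP-glycosyltransferase gene (-4.28, edgeR Benjamini-Hochberg adjusted p = 0.00882), CG9825 (-3.78) and CG18765 (-3.36). LManIII, a lysosomal alpha-mannosidase gene (-4.26), the antimicrobial peptide gene Mtk (-3.55), loaf (-3.46) and the cytochrome P450 gene Cyp4d1 (-3.37) also passed. These last 4 calls were lost by edgeR without any mutant library, except that Mtk kept its call without the deletion mutant's replicate 1, and the adjusted p reached 0.129 for LManIII, 0.120 for Mtk, 0.0572 for loaf and 0.119 for Cyp4d1 (Benjamini-Hochberg). Replicate 2 of both controls had the same effect on LManIII, Mtk and Cyp4d1, and replicate 1 of FRT19A on Mtk and Cyp4d1.

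In all, 608 genes were higher and 840 lower among 13244 tested by edgeR with Benjamini-Hochberg adjustment (3438 at an unadjusted p under 0.05). The blocked fit called 1634 higher and 2543 lower. SE libraries alone gave 0 calls by edgeR (3046 at an unadjusted p under 0.05) and PE libraries alone 4875. Leaving out W1118 replicate 1 raised the total to 1783. Leaving out any other library lowered it: to 968 and 705 for FRT19A replicates 1 and 2, 627 for W1118 replicate 2, 445 and 481 for the point mutant's replicates 1 and 2, and 596 and 458 for those of the deletion mutant.

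JAK-STAT signalling genes and targets, a pathway of gut repair and stress, rose together: 9 of 12 members were called higher (9 adjusted over the list alone), with a median log2 of 3 (camera with Benjamini-Hochberg adjustment, adjusted p = 4.26e-10; adjusted p = 0.0549 with an estimated correlation). Socs36E, a feedback inhibitor of the pathway (2.63, SE 0.20), TotA (6.70) and TotB (5.48) had the smallest edgeR adjusted p in the list. Of 12 antimicrobial peptide genes, 4 rose and 1, Mtk, fell (8 and 1 adjusted over the list alone; blocked fit 8 and 1), with AttB (4.99), Drs (4.45) and Dro (4.81) among the rises and a median of 2.87 (camera adjusted p = 4.78e-05 after Benjamini-Hochberg adjustment; adjusted p = 0.269 with an estimated correlation). Among 22 Imd and Toll pathway genes, which switch those peptides on, 4 rose and 0 fell (4 adjusted over the list alone), among them dl (0.88), Rel (0.75) and spz (1.38), and the list as a whole did not stand apart (median 0.19, camera adjusted p = 0.253 after Benjamini-Hochberg adjustment). JNK stress genes had 2 of 10 called higher, Jra (0.93) and kay (1.24), and the EGFR pathway 2 of 9, rho (1.52) and its inhibitor sty (0.84) (each 2 adjusted over the list alone), with list medians of 0.36 and 0.28 and camera adjusted p = 0.364 and 0.204 (Benjamini-Hochberg). Among 24 DNA damage and cell death genes 5 rose and 2 fell (6 and 2 adjusted over the list alone), with the transcription factor Ets21C at 2.57, the cell death gene hid at 2.39 and the ribonucleotide reductase gene RnrL at -1.43 (list median 0.09, camera adjusted p = 0.465 after Benjamini-Hochberg adjustment). Counts in the blocked fit were 7 higher and 3 lower for Imd and Toll genes, 2 and 1 for JNK genes, 4 and 1 for EGFR genes and 7 and 4 for DNA damage and cell death genes. The calls of Rel, spz, rho, sty and kay were each lost on leaving out any of 5 to 8 libraries taken 1 at a time, with edgeR Benjamini-Hochberg adjusted p up to 0.0962, 0.0981, 0.0597, 0.0992 and 0.0827.

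Genes of the piRNA pathway, which silences transposable elements mainly in the germline, were higher: 11 of 32 were called (11 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 4.44e-06 after Benjamini-Hochberg adjustment; adjusted p = 0.0735 with an estimated correlation). AGO3, a germline Argonaute protein, rose by 5.26 (SE 0.30, edgeR Benjamini-Hochberg adjusted p = 0.000917), tapas by 1.34 and BoYb by 3.85. The list median was 0.81 in SE and 0.92 in PE libraries. Testis and male germline markers moved beside it, with a median of 1.09 over 25 genes (camera adjusted p = 0.00183 after Benjamini-Hochberg adjustment; adjusted p = 0.894 with an estimated correlation). In SE libraries the testis median was 0.46 and in PE libraries 4.38, where 17 of 22 were called higher. Over all libraries 1 testis marker passed, bam, a gene of germ cell differentiation (2.54; 0 adjusted over the list alone), and its edgeR call was lost on leaving out any library (Benjamini-Hochberg adjusted p up to 0.108). The blocked fit called 3 testis markers higher (median 2.20). The siRNA pathway, a further silencing route, had 1 of 5 genes called higher, AGO2 (0.68; list median -0.11, camera adjusted p = 0.881 after Benjamini-Hochberg adjustment), and heterochromatin factors 1 of 19, ADD1 (0.87; list median -0.17, camera adjusted p = 0.375). Adjusted over the list alone, AGO2 and ADD1 passed and 1 siRNA gene also fell, and the blocked fit called 1 siRNA gene higher and 1 lower and 2 heterochromatin factors higher and 4 lower. The calls of AGO2 and ADD1 over all genes were each lost without 7 of the 8 libraries (edgeR Benjamini-Hochberg adjusted p up to 0.127 and 0.0860), AGO2 keeping its call without FRT19A replicate 1 and ADD1 without the deletion mutant's replicate 1.

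Genes of energy and protein production were lower. Of 87 oxidative phosphorylation genes, which encode the mitochondrial respiratory chain, 29 fell and 1 rose (42 and 2 adjusted over the list alone; blocked fit 60 and 2), with a median of -0.67 (camera adjusted p = 2.53e-07 after Benjamini-Hochberg adjustment; adjusted p = 0.269 with an estimated correlation). The complex I genes ND-20 (-0.92, SE 0.11), ND-PDSW (-0.91) and ND-B16.6 (-0.89) were among them. In PE libraries alone 61 were called lower and 19 higher, beside a testis marker median of 4.38 there. Of 90 ribosomal protein genes 11 fell and 1 rose (20 and 1 adjusted over the list alone; blocked fit 78 and 2), with a median of -0.47 (camera adjusted p = 2.43e-10 after Benjamini-Hochberg adjustment; adjusted p = 0.257 with an estimated correlation). The rise was that of RpS5b, a paralog used in the germline (3.47), and the falls included RpLP0-like (-1.12) and RpL36A (-0.58). RpLP0-like lost its edgeR call without the deletion mutant's replicate 2 (Benjamini-Hochberg adjusted p = 0.0550), and RpL36A without any mutant library or replicate 2 of either control (up to 0.0776). Of 31 cell cycle and DNA replication genes 10 fell and 0 rose (10 adjusted over the list alone), among them the replicative helicase genes Mcm6 (-1.45), dpa (-1.40) and Mcm3 (-1.81), with a median of -0.30 (camera adjusted p = 0.00561 after Benjamini-Hochberg adjustment; adjusted p = 0.269 with an estimated correlation).

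**Figure D3:**
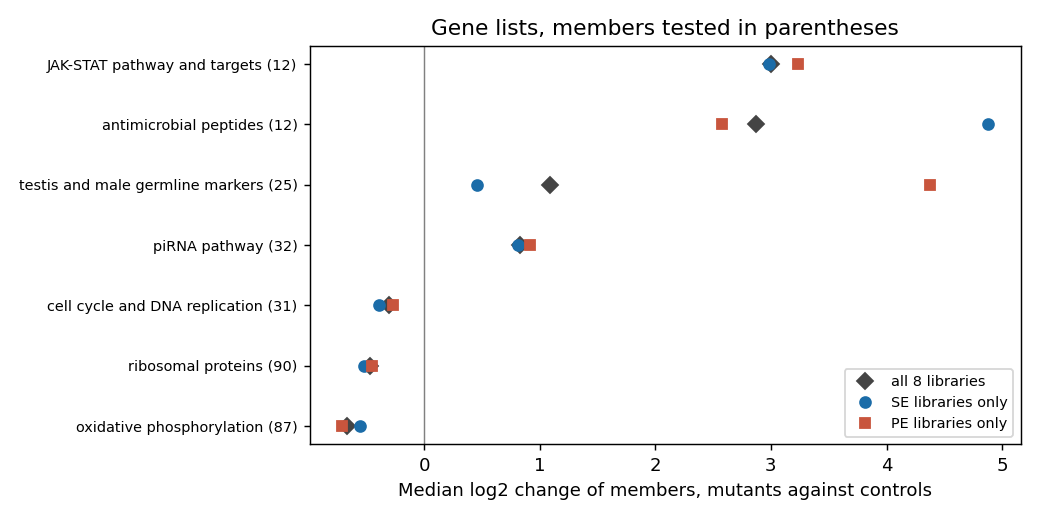
Median log2 fold change of gene lists between mutants and controls, in all pharate libraries and in SE or PE libraries alone. The JAK-STAT median is 3 and the oxidative phosphorylation median -0.67 over all libraries, and the testis median is 0.46 in SE and 4.38 in PE libraries.

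Gut cell type markers moved in part. Of 15 enteroendocrine markers (genes of the gut's hormone cells) 3 fell, the tachykinin gene Tk (-1.04) and the prohormone processing genes 7B2 (-0.77) and amon (-0.70), with a list median of -0.70 (camera adjusted p = 0.0524 after Benjamini-Hochberg adjustment; 6 lower and 1 higher adjusted over the list alone). The median was also -0.70 in SE libraries and in PE libraries (camera adjusted p = 0.127 and 0.0478 at the preset correlation only). PE libraries alone had 6 markers called lower and 1 higher. Of 21 enterocyte markers (the absorptive cells) 3 fell and 1 rose (the same counts adjusted over the list alone), with ninaD, a carotenoid uptake gene, at -2.49, the trypsin gene zetaTry at -1.82 and the myosin gene Myo31DF at 0.62 (list median -0.30, camera adjusted p = 0.265; 0.09 in SE libraries, and -0.57 with an adjusted p = 0.00621 in PE libraries, at the preset correlation only). Malpighian tubule markers split: 3 of 17 rose and 3 fell (3 and 4 adjusted over the list alone), with the urate oxidase gene Uro at 4.36, the transporter gene Oatp58Db at 1.68 and Tsf1, an iron carrier gene, at 2.32 (list median -0.35, camera adjusted p = 0.586 after Benjamini-Hochberg adjustment). In copper cell and lysozyme genes, of the acid-secreting gut region, 1 of 9 rose, LysP (5.82; median 1.09, camera adjusted p = 0.0524, in SE libraries 0.42 and 0.0154, in PE libraries 1.30 and 0.321, both at the preset correlation only; 1 adjusted over the list alone). Of 10 intestinal progenitor markers 1 rose, E(spl)malpha-BFM, a Notch target (1.99; 2 adjusted over the list alone), while the list median was -0.02, and 0.04 in the blocked fit (camera adjusted p = 0.592). With the block 2 enteroendocrine markers were higher and 8 lower, and 2 enterocyte markers higher and 6 lower. The same fit called 3 copper cell and lysozyme genes higher and 1 lower, and 2 progenitor markers higher. Except for Tk, LysP and E(spl)malpha-BFM, each gene named in this paragraph lost its edgeR call without at least 3 of the 8 libraries taken 1 at a time, with Benjamini-Hochberg adjusted p up to 0.150 (amon without the point mutant's replicate 1). Uro kept it without any control library and lost it without the point mutant's replicate 1 (0.0521).

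Among digestive and detoxification genes, calls of the main fit covered at most a small part of each list. Jonah serine proteases had 0 of 16 called by edgeR over all genes or adjusted over the list alone (median 0.45, camera adjusted p = 0.260 after Benjamini-Hochberg adjustment). Their median was 1.66 in SE libraries (camera adjusted p = 5.60e-07 after Benjamini-Hochberg adjustment, at the preset correlation only) and -0.41 in PE libraries (0.321), where 2 genes were called lower. Amylases and maltases had 2 of 13 called higher, Amy-d (2.08) and Amy-p (1.61) (2 adjusted over the list alone; median 0.11, camera adjusted p = 0.254; 0.86 and 0.00569 in SE libraries, 0.15 and 0.951 in PE libraries). Of 78 cytochrome P450 genes 5 rose and 7 fell (6 and 11 adjusted over the list alone), with Cyp4p1 at 2.55, Cyp313a4 at -2.12 and Cyp4ad1 at -1.95 (median -0.19, camera adjusted p = 0.586). Of 32 glutathione transferase genes 4 fell, among them GstE11 (-0.99), GstE5 (-2.22) and GstD4 (-2.48) (4 lower and 1 higher adjusted over the list alone; median -0.23, camera adjusted p = 0.282; -0.05 and 0.876 in SE libraries, -0.31 and 0.0497 in PE libraries). Of 18 lipid metabolism genes 1 rose, the triglyceride lipase gene bmm (0.90; 1 adjusted over the list alone; median 0.41, camera adjusted p = 0.156; blocked fit 0.42, 0.0373, and there adjusted p = 0.682 with an estimated correlation; 0.50 and 0.0150 in SE libraries, 0.39 and 0.321 in PE libraries). In the mitochondrial and ER stress list Thor, a translation inhibitor, rose (1.82) and 3 genes fell, among them the chaperone genes Hsp60A (-1.05) and Hsc70-3 (-1.04), of 11 tested (2 higher and 4 lower adjusted over the list alone; median 0.24, mean -0.03, camera direction down, adjusted p = 0.860 after Benjamini-Hochberg adjustment). Heat shock proteins had 1 of 16 called lower, Hsc70-3 (median -0.42, camera adjusted p = 0.375; 1 adjusted over the list alone). The direction of this list turned between SE libraries (median 0.81, camera adjusted p = 0.00393 after Benjamini-Hochberg adjustment) and PE libraries (-0.95, 0.00945), both at the preset correlation only. Values for SE or PE libraries in this paragraph are at the preset correlation only. With the block 1 Jonah gene was higher, 3 amylase and maltase genes higher and 1 lower, and 9 cytochrome P450 genes higher and 20 lower. That fit called 8 lipid metabolism genes higher and 2 lower, 4 mitochondrial and ER stress genes higher and 4 lower, 1 heat shock gene higher and 1 lower, and 1 glutathione transferase gene higher and 5 lower. Amy-d, Amy-p, the 3 glutathione transferase genes, bmm, Hsp60A and Hsc70-3 each lost their edgeR call without 4 to 7 of the 8 libraries taken 1 at a time, with Benjamini-Hochberg adjusted p up to 0.133 (GstD4 without the point mutant's replicate 1).

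Of 51 cuticle protein genes 2 rose, TwdlG (5.74) and Edg91 (5.16), and 2 fell, 1 of them Cpr51A (-2.02) (2 and 1 adjusted over the list alone; median -0.28, mean 0.08, camera adjusted p = 0.689 after Benjamini-Hochberg adjustment). Edg91 lost its edgeR call without the point mutant's replicate 1 (Benjamini-Hochberg adjusted p = 0.0521) and Cpr51A without that mutant's replicate 2 (0.0503). The 22 ecdysone response genes, which follow the moulting hormone, had 0 calls by edgeR over all genes or adjusted over the list alone (median 0.07, camera adjusted p = 0.465), and 0 of the 8 Eig71E genes had enough counts to be tested. Fat body markers had 1 of 11 called higher, bmm, and 1 lower, the alcohol dehydrogenase gene Adh (-2.44; 1 and 1 adjusted over the list alone), with a median of 0.58, and -0.07 in the blocked fit (camera adjusted p = 0.883 after Benjamini-Hochberg adjustment). bmm and Adh lost their edgeR calls without any of 4 libraries taken 1 at a time, among them both point mutant libraries (Benjamini-Hochberg adjusted p up to 0.0594 and 0.0680). Visceral muscle (18 genes, median -0.36, camera adjusted p = 0.0844; blocked fit -0.35, 0.0210, and there adjusted p = 0.682 with an estimated correlation; SE libraries -0.39, 0.0126 at the preset correlation only), tracheal (7, -0.69, 0.465), haemocyte (9, -0.12, 0.743), male accessory gland (15, 0.01, 0.586) and nervous system markers (13, 0.01, 0.899) had 0 calls by edgeR over all genes or adjusted over the list alone. The blocked fit called 4 cuticle genes higher and 5 lower, 2 ecdysone response genes higher, and 3 fat body markers higher and 1 lower. It also called 1 visceral muscle marker higher and 6 lower, 3 tracheal markers lower, 2 haemocyte markers higher, and 2 nervous system markers higher and 1 lower. Of the 35 lists tested, 7 passed camera with Benjamini-Hochberg adjustment, all 7 also without each library in turn, and 0 passed with an estimated correlation. In the blocked fit 9 passed and 0 with an estimated correlation.

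Each allele was also set against FRT19A. In the deletion mutant G_element rose by 7.26 (SE 1.49) and GATE by 6.16 (SE 1.16), each with an edgeR Benjamini-Hochberg adjusted p = 0.0455. Both calls were lost without FRT19A replicate 1 (0.352) or replicate 2 (0.109), and that of G_element also without the deletion mutant's replicate 1 (0.0522). These were the 2 families called in the deletion mutant (43 at an unadjusted p under 0.05; blocked fit 90 higher and 1 lower; 47 by DESeq2), and 0 were called in the point mutant by edgeR (39 unadjusted; blocked fit 80 higher and 2 lower; 42 by DESeq2). Median changes over the families were 2.07 and 1.65. No gene passed by edgeR in either allele: 0 in the deletion mutant (1949 at an unadjusted p under 0.05; blocked fit 532 higher and 961 lower; 1050 by DESeq2) and 0 in the point mutant (1840; blocked fit 443 higher and 663 lower; 979 by DESeq2). In simulated data the fit without the block recovered 0% of genes changed 4-fold for the deletion mutant against FRT19A. Its 0 calls therefore do not show an absence of change. The authors' deposited table listed 3747 genes and 102 element families past an adjusted p of 0.05 for the deletion mutant and 3618 and 95 for the point mutant. HIS1 was at -7.34 in the deletion mutant (SE 2.78, edgeR Benjamini-Hochberg adjusted p = 0.312) and at -6.52 in the point mutant (SE 2.67, 0.365).

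List medians of the alleles share the FRT19A libraries, so they are alike in part by construction, and their difference was not tested. JAK-STAT genes had medians of 3.21 in the deletion mutant and 3.35 in the point mutant, antimicrobial peptide genes 4.64 and 4.60, piRNA pathway genes 1.02 and 0.75, ribosomal protein genes -0.51 and -0.57, and oxidative phosphorylation genes -0.76 and -0.68. Enteroendocrine markers had medians of -0.94 and -0.83, and W1118 against the same FRT19A libraries had -0.42 (camera adjusted p = 0.000210 after Benjamini-Hochberg adjustment; adjusted p = 0.632 with an estimated correlation). Each of these lists passed camera with Benjamini-Hochberg adjustment in both alleles, with an adjusted p of 0.00251 for enteroendocrine markers of the deletion mutant the highest among them, and none with an estimated correlation (adjusted p from 0.122 to 0.279 with an estimated correlation). Male accessory gland markers, genes of seminal fluid proteins, had medians of 6.83 and 6.84 against FRT19A (camera adjusted p = 0.00118 and 1.10e-06 after Benjamini-Hochberg adjustment; adjusted p = 0.909 and 0.508 with an estimated correlation). The value of the deletion mutant rests on 1 library: summed accessory gland markers were at 2.31 CPM in its replicate 1 and 386 CPM in its replicate 2, against 1.49 and 1.98 CPM in FRT19A.

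The control strains were compared to give the background between strains. copia was 3.66 higher on the log2 scale in W1118 than in FRT19A (SE 1.48, edgeR Benjamini-Hochberg adjusted p = 0.529; blocked fit 3.62, 0.000208), against 5.50 for the deletion mutant over FRT19A (0.0605; blocked fit 5.57, 2.98e-05). P_element, a DNA transposon carried by some strains and chosen after its values were seen, stood at -7.74 in W1118 (SE 1.54, edgeR Benjamini-Hochberg adjusted p = 0.0736; blocked fit -7.31, 0.00459). The median over all families was 0.09, and 0 families were called by edgeR (9 at an unadjusted p under 0.05; 5 by DESeq2; blocked fit 10 higher and 4 lower). Accessory gland markers had a median of 7.77 in W1118 over FRT19A (camera adjusted p = 8.23e-18 after Benjamini-Hochberg adjustment; adjusted p = 0.632 with an estimated correlation). Antimicrobial peptide genes had a median of 1.29 there (camera adjusted p = 0.00447 after Benjamini-Hochberg adjustment, and 0.686 with an estimated correlation). Ribosomal protein genes were at -0.13 (camera adjusted p = 0.0303, and 0.686 with an estimated correlation). Oxidative phosphorylation genes were at -0.15 (camera adjusted p = 0.0451, and 0.790 with an estimated correlation). Malpighian tubule markers (-0.28), DNA damage and cell death genes (-0.30) and cuticle genes (0.40) also passed camera with Benjamini-Hochberg adjustment (0.0175, 0.0175 and 0.00905). None of these lists passed with an estimated correlation. Among genes 0 were called by edgeR (606 at an unadjusted p under 0.05, 262 by DESeq2 and 1 in the blocked fit), and the authors' deposited table listed 653. This comparison came from the same fit as those of the alleles, so its 0 calls do not show that the strains are alike.

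The alleles were then compared with each other. GATE differed by 0.16 (SE 0.93), G_element by 0.34 (SE 1.13) and copia by 0.02 (SE 1.33) on the log2 scale between the deletion and the point mutant, each with an edgeR Benjamini-Hochberg adjusted p = 0.999. No gene was called by edgeR (34 at an unadjusted p under 0.05, 8 by DESeq2; blocked fit 0, with 189 unadjusted), and 0 element families (0 unadjusted; blocked fit 0, with 2 unadjusted). Since the same fit was used, these 0 calls do not show that the alleles are alike. Fold changes of both alleles against FRT19A correlated across 13244 genes with r = 0.951 (rho 0.943) and a covariance of 2.21, against a simulated r = 0.497 and covariance of 0.507 for unchanged groups that share the control. With controls split between the alleles, so that the comparisons share no library, r was 0.499 and 0.525; that setting was not simulated. Without the deletion mutant's replicate 2 the r with the shared control fell to 0.597. For element families r was 0.986 with the shared control (simulated 0.446), 0.655 and 0.607 with split controls. In the blocked fit 389 genes were called higher in both alleles and 594 lower in both (independent lists would share 17.8 and 48.1). With split controls 291 and 281 were higher in both and 224 and 282 lower in both (independent lists would share 16.1 to 22.4). Genes are not independent replicates, and part of the excess with the shared control may come from that control.

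The adult libraries addressed whether supplying Hinfp or His1 returned the mutant gut towards control. With 1 library per genotype these differences have no replicate check and carry no p-values, and the His1 level itself was not analysed here. Hinfp had 244 counts in the adult control (exact Poisson interval 214 to 277), 95 in the mutant (76.9 to 116), 28734 in the Hinfp rescue and 114 in the His1 rescue (94.0 to 137). Element counts made up 1.70% of all counts in the control (95% Wilson interval 1.69 to 1.70), 16.6% in the mutant (16.5 to 16.6), 4.11% in the Hinfp rescue (4.10 to 4.12) and 4.48% in the His1 rescue (4.47 to 4.48). Of these element counts copia made up 41078 of 350348 in the control and 2625652 of 3572262 in the mutant. It made up 317994 of 770380 in the Hinfp rescue and 436520 of 853248 in the His1 rescue. The high share in the mutant therefore rests in large part on copia, whose strain difference was not told apart from rescue. Testis markers also fell from the mutant to both rescues. Their medians were 6.99 in the mutant, -0.58 in the Hinfp rescue and -0.34 in the His1 rescue in the authors' deposited table (7.01, -0.07 and -0.05 with a floor of 3 counts). In the rescues these markers thus stood near or below control, while the element share stayed above it. In the authors' deposited table a total of 104 families were at least 1 higher on the log2 scale in the mutant, 34 in the Hinfp rescue and 82 in the His1 rescue, with medians of 2.01, 0.60 and 1.11. All 47 families called in the pharate mutants were at least 1 higher in the adult mutant in the authors' deposited table, 12 of them in the Hinfp rescue and 39 in the His1 rescue.

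**Figure D4:**
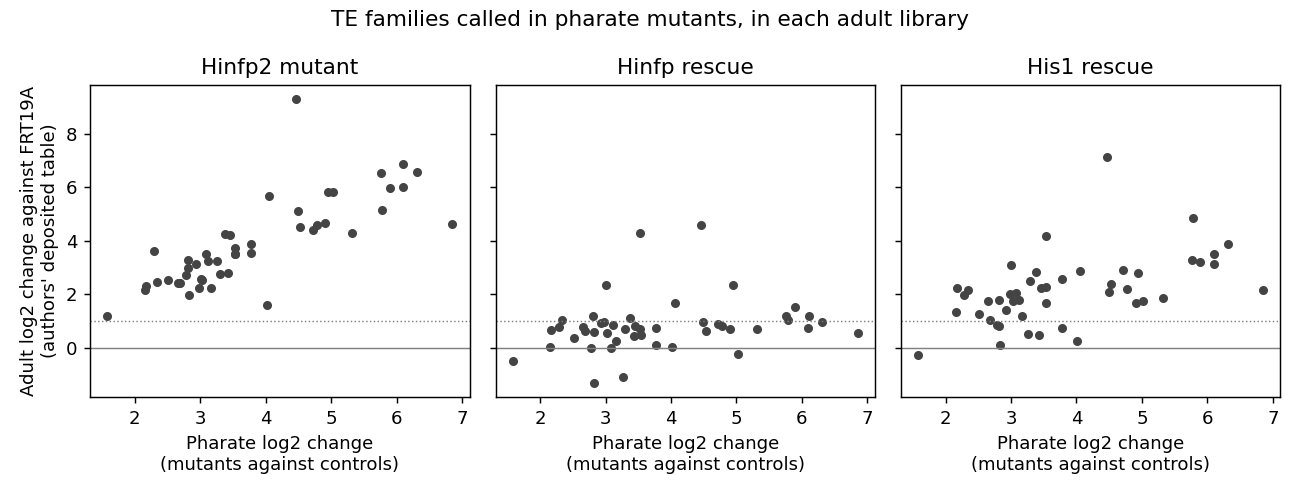
The authors' log2 fold changes in the adult mutant and both rescues against the adult control, 1 library each, set against the pharate change. The families drawn are the 47 called in the pharate mutants. Their medians are 3.52 in the mutant, 0.72 in the Hinfp rescue and 2.04 in the His1 rescue.

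Single families differed between the rescues. For GATE the authors' deposited table gave log2 changes of 6.01 in the mutant, 1.19 in the Hinfp rescue and 3.50 in the His1 rescue and for copia 5.93, 3.09 and 3.52. In the same authors' deposited table accord stayed above the FRT19A control (9.30, 4.58 and 7.15). Among the pharate controls copia was also higher in W1118 than in FRT19A, as given above, and the only adult control was FRT19A. For copia a strain difference was therefore not told apart from incomplete rescue. The same limit holds for accord, which was measured against the same single adult control. The strain background of the adult mutant and rescues was not tested for any family. The LTR retrotransposon roo was at -0.24 in the mutant, 3.13 in the Hinfp rescue and 0.61 in the His1 rescue in the authors' deposited table.

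Genes called higher in pharate mutants were higher in the adult mutant and less so in the rescues. Those of the 608 pharate genes with an adult value (587, 544 and 554) had medians of 2.23 in the mutant, 0.74 in the Hinfp rescue and 0.90 in the His1 rescue in the authors' deposited table, and the 840 lower genes -1.36, -0.80 and -0.79. These adult changes follow counts scaled to totals that include elements, 16.6% of all counts in the mutant. The median over well-counted genes was -0.23 in the mutant, -0.03 in the Hinfp rescue and -0.05 in the His1 rescue. Adult values in this report were not corrected for that offset. JAK-STAT genes had medians of 4.51, 2.35 and 3.12 in the authors' deposited table, at the percentiles 99.99, 100 and 100 among 10000 random lists matched on expression. The stress gene TotA was at 7.79, 5.44 and 7.26, and Uro at 4.35, 2.53 and 3.23, in the authors' deposited table. AGO3 had 9 counts in the control, 1361 in the mutant, 14 in the Hinfp rescue and 42 in the His1 rescue, and piRNA pathway genes had medians of 1.36, 0.12 and 0.02 in the authors' deposited table (percentiles 99.69, 85.48 and 56.2). Testis markers were at 7.01, -0.07 and -0.05 in the same libraries with a floor of 3 counts. In pharate SE libraries the median log2 change was 0.46 for testis markers and 0.81 for piRNA pathway genes. AGO3 stood there at 2.002 and 2.103 CPM in controls and 49.3 and 59.4 CPM in mutants. AGO3 thus rose by more than the testis marker median in those pharate libraries. In the adult libraries, where both moved together, testis content was not told apart from the change of these germline genes. Antimicrobial peptide genes stayed high, with medians of 7.64, 9.77 and 7.54 in the authors' deposited table, or 4.05, 5.92 and 4.58 when a floor of 3 counts per library stands for the 9 of 14 genes at 0 in the control. Oxidative phosphorylation genes stayed low in all (-1.09, -0.79 and -1.02, each at the percentile 0 in the authors' deposited table). The adult control was given as 5 to 6 days old and the mutant and both rescues as 8 to 9 days. For any adult change shared by the mutant and both rescues, age was therefore not told apart from incomplete rescue.

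Among single genes with large adult changes, Drsl3 had 0 control counts and 7521 in the mutant, at least 2396-fold higher, at least 107-fold in the Hinfp rescue and at least 138-fold in the His1 rescue, against 3 counts per library. DptA, the Diptericin peptide gene, was at least 82.8-fold, 1881-fold and 586-fold higher. Mst84Dd, a sperm protein gene, had 0, 1255, 3 and 2 counts in the control, mutant, Hinfp rescue and His1 rescue. LManIII was at -6.18 in the mutant, -0.83 in the Hinfp rescue and -0.81 in the His1 rescue in the authors' deposited table. Akh, the adipokinetic hormone gene, had 873, 13, 501 and 395 counts and Burs, which encodes a hormone subunit of cuticle hardening, 190, 0, 57 and 50 in the control, mutant, Hinfp rescue and His1 rescue.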

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

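The tests that weigh explanations in this part were chosen after the results were seen. Element families rose in the mutants: in SE libraries, where testis markers differed by a median of 0.46 (quartiles 0.24 to 0.64), the median element change was 2.22 (quartiles 0.55 to 3.65), which argues against testis tissue carried into mutant dissections as the whole source. Gene library totals without TMM gave a median of 1.77. TMM factors lay between 0.882 and 1.18 and both settings scale on gene counts. Leaving the factors out could therefore move the median little and cannot decide on scaling. Of 35 splits of the libraries, 1 (the real one) reached 47 called families and the highest other, which set SE against PE libraries, reached 39, while the 18 splits balanced over SE and PE are too few for a share under 0.05 (real value 47, highest other 0). W1118 against FRT19A had a median of 0.09, and the alleles had 2.07 and 1.65 against FRT19A and 1.95 and 1.80 against W1118, so a difference between these control strains does not account for the rise, while the mutants' own background was not tested. Age stays open. The adult Hinfp rescue, given the same age range as the mutant, had a median of 0.597 against 2.01 in the mutant. Testis markers were also high in that mutant and near or below control in that rescue. With 1 library per genotype and no older pharate control, age and the loss of Hinfp cannot be told apart in the pharate libraries.

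Testis transcripts such as those of the list with bam were higher in PE mutants than in PE controls. Over 473 genes near 0 in the adult control and high in the adult mutant, SE controls exceeded PE controls by a median log2 of 3.55, which is what testis tissue in some dissections would give. That difference was 2.59 larger in controls than in mutants, where it was 0.939, so a fixed difference between SE and PE preparation does not account for it. In SE libraries mutants exceeded controls by 0.574 (quartiles 0.44 to 0.71) and in PE libraries by 3.18. A rise of these transcripts through loss of Hinfp stays open, since transcripts already present in SE controls could hide it.

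HIS1 fell further than the core histones. In PE libraries its change lay 6.46 below that of the core histone with the largest fall, which argues against fewer dividing cells as the whole source. Within SE libraries HIS1 changed by -3.66, which argues against low capture of histone transcripts there. HIS1 in W1118 against FRT19A was at 0.38 (blocked fit 0.12). Shared reads among histone gene copies, the mutants' own background and age were not tested and stay open.

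The split count over all genes gave 2 of 35 splits with at least the real 1448 calls, so a chance division of the libraries cannot be excluded by it; the other split set SE against PE libraries and called 2624, which points to that structure of the samples, and the blocked fit called 4177. With the block, 18 splits are too few for a share under 0.05 (real value 4177 genes, highest other 0).

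Chance puts about 1 in 20 groups past the limit used for a sample far from the other 3 of its class, and 13 of 252 groups passed it. The ratio of gap to range was 0.859 for TotC in mutants (point mutant replicate 1 at 6.79 log2 CPM, others 8.75 to 9.07). It was 0.875 for loaf in controls (FRT19A replicate 2 at 1.91, others 4.51 to 4.88). Cyp4d1 had 0.873 in mutants (deletion replicate 2 at -0.45, others 0.64 to 0.79). For spz in controls it was 0.834 (W1118 replicate 2 at 1.62, others 2.67 to 2.88) and for rho 0.874 (W1118 replicate 1 at 3.37, others 2.64 to 2.74). In mutants sty had 0.960 (point replicate 1 at 8.23, others 8.04 to 8.05) and GstE11 0.873 (point replicate 1 at 2.75, others 3.06 to 3.10). In controls BoYb had 0.847 (FRT19A replicate 2 at -0.88, others -0.55 to -0.49) and E(spl)malpha-BFM 0.987 (FRT19A replicate 2 at 0.82, others 0.33 to 0.34). List means far from the others were those of ecdysone response genes (0.916, W1118 replicate 1 at 5.00, others 3.92 to 4.01) and cuticle genes (0.877, the same library at 1.63, others 0.50 to 0.64) in controls. In mutants they were those of ribosomal protein genes (0.844, point replicate 1 at 7.93, others 8.05 to 8.08) and oxidative phosphorylation genes (0.841, point replicate 2 at 5.50, others 5.31 to 5.34).

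The mutant effect differed between SE and PE libraries by edgeR with Benjamini-Hochberg adjustment for 804 genes (769 higher and 35 lower in PE), 20 element families (1 higher, Bari1, and 19 lower) and 11 of 25 testis markers, all 11 higher in PE.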

How the results depend on the processing

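The tests added after the data were seen were DESeq2 with the block, list tests on SE or PE libraries alone or without each library, and allele agreement with the block or without each library. Of 1264 alternative values for named genes, 947 kept direction and call, 314 lost the call, 3 gained it and 0 reversed; 191 of the losses came from leaving out 1 library, 78 from SE libraries alone, 33 from the mean of groups, 7 without the count filter and 5 from PE libraries alone. The 33 were HIS1, Jra and 31 other genes for which the report names a call lost without 1 library. For named element families 209 of 214 kept their call, and for lists 163 of 177. Where a cause is not given below, the cause was not tested.

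Genes between mutants and controls (1448) numbered 4177 with the replicate block, 2701 by DESeq2, 6398 by DESeq2 with the block, 912 with a fold limit, 436 with the mean of groups, 0 in SE and 4875 in PE libraries, and 445 to 1783 without 1 library. The deletion mutant (0) had 1493 with the block, 13 with DESeq2 size factors, 1050 by DESeq2 and 3748 by DESeq2 with the block. The point mutant (0) had 1106, 17, 979 and 3613, and 7 without the count filter. W1118 against FRT19A (0) had 1 with the block, 262 by DESeq2 and 644 by DESeq2 with the block, and deletion against point (0) 8 by DESeq2 and 33 with DESeq2 and the block. Without 1 library all 4 stayed at 0 to 0.

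Element families between mutants and controls (47) numbered 96 with the block, 99 by DESeq2 with the block, 78 in SE and 86 in PE libraries, and 39 to 49 without 1 library. The deletion mutant (2) had 91 with the block, 17 with DESeq2 size factors, 47 by DESeq2, 11 with only the compared groups, 5 against W1118, 18 with scaling on the elements, 27 without TMM, 100 by DESeq2 with the block, and 0 to 11 without 1 library. The point mutant (0) had 82, 1, 42, 11, 2, 17, 23 and 96 in the same order, and 0 to 10. W1118 against FRT19A (0) had 14 with the block, 5 by DESeq2, 1 with only the compared groups, 5 with scaling on the elements, 31 by DESeq2 with the block, and 0 to 1. Deletion against point stayed at 0 to 0.

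List tests (7) numbered 0 with an estimated correlation, 13 in SE and 12 in PE libraries, 9 with the block, and 7 to 13 without 1 library. The intestinal progenitor median (-0.02) was 0.0354 with the block and 0.0189 with DESeq2 size factors. The fat body median (0.58) was -0.0735 with the block. The accessory gland median (0.01) was -0.0288 with size factors and -1.38 in SE libraries. Allele agreement over genes (r = 0.951) was 0.499 and 0.525 with split controls, 0.954 with the block and 0.597 to 0.974 without 1 library; over families (0.986) it was 0.655, 0.607, 0.982 and 0.847 to 0.991.

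In the adult set, with a limit of 2 on the log2 scale in place of 1, 4958 genes passed in the mutant, 2644 in the Hinfp rescue and 2680 in the His1 rescue, and 17 and 39 families in the rescues. With 0.5 the rescues had 7734 and 7918 genes, and the Hinfp rescue 102 families; these follow from the limits. With the count filter 13244 genes were tested, and whether depth limits calls for rare transcripts was not tested.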

Other observations

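In the adult rescues digestive genes stood above the control. No weighing test was run in this part, and the genes outside the lists were picked by size of change. Jonah serine proteases, which digest protein, had medians of -1.43 in the mutant, 1.59 in the Hinfp rescue and 1.95 in the His1 rescue in the authors' deposited table (percentiles 0, 100 and 100). Copper cell and lysozyme genes had -0.04, 2.86 and 3.02 there, amylases and maltases, which digest starch, -0.59, 0.91 and 0.88, and intestinal progenitor markers -0.38, 0.72 and 1.34, all in the authors' deposited table. Enterocyte markers were at -1.14, 0.23 and 0.05 in the authors' deposited table. Each genotype had 1 library.

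Mov10, an RNA helicase gene, had 3 counts in the adult control, 834 in the mutant, 580 in the Hinfp rescue and 2517 in the His1 rescue. The eye colour gene w had 0, 8, 1899 and 1616 counts, and the element Dmau_mariner 0, 0, 128 and 310. Whether the counts of w and Dmau_mariner follow the genetic background of the rescues or a change of expression was not tested. Male accessory gland markers had medians of -0.82, -4.85 and -8.46 in the authors' deposited table (-0.82, -4.44 and -7.27 with a floor of 3 counts per library).

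P_element stood at 26.9 and 238 CPM in FRT19A, 0.396 and 0.843 in W1118, 73.1 and 136 in the point mutant and 67.7 and 147 in the deletion mutant (SE and PE libraries). Summed accessory gland markers were at 1.49 and 1.98 CPM in FRT19A, 531 and 134 in W1118, 284 and 170 in the point mutant and 2.31 and 386 in the deletion mutant.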
